A study of Homo sapiens with 6 samples.

How the data were processed

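Total RNA of temozolomide-resistant and temozolomide-sensitive U251 cells was amplified, labelled with the red dye Cy5 and hybridised to single-colour arrays for long noncoding and messenger RNA, per the labels' protocols. The groups and replicate numbers were taken from the sample titles, which give 3 arrays per group. The labels' protocols give RNA quality limits for the study as a whole and no value per sample.

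The deposited scanner files hold spot intensity on a linear scale, and were made by Agilent Feature Extraction 10.7.3.1 from the red channel only, per the file headers. The processed intensity is background-subtracted by that program and not scaled between arrays, per the file headers and the values. R 3.3.0 and limma are named without a role, per the submitters' processing notes. The authors also deposited a value table of the same arrays. Set against the scanner intensity, its columns equalled normexp background correction (no offset) of the median spot and background signals times 1 factor per array, within 1% at 100% of probes. These factors were 1.08, 1.12 and 1.08 for the resistant arrays and 1.18, 0.81 and 0.80 for the sensitive arrays. Every column of the table had a median of 179.8, so its scale is linear and each array is centred on its median. Every column of the table matched a sample.

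For the main results, the log2 processed intensity of each array was reduced by the array's 75th percentile over the hs- and lnc-prefixed probes. Spots marked as outliers by Feature Extraction (3, 2 and 11 on the resistant arrays, 1, 14 and 45 on the sensitive arrays) were left out, and control spots were not tested. A probe was tested when it was well above background, by the program's own mark, on all 3 arrays of at least 1 group. The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, and p-values were adjusted by Benjamini-Hochberg over the 30978 probes tested, with a threshold of 0.05. The tested share was 68.3% of hs-prefixed and 40.1% of lnc-prefixed probes. Signal over background sets which probes could be tested, and 3 arrays per group set the precision, with a median SE of 0.12 log2 units.

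Where no array of a group was well above background, the fold is a bound. It is the bright group's mean log2 value against the dim group's mean of, on each array, the higher of the lowest value among probes well above background and the probe's own value. Probes seen on some arrays of the dim group kept their fitted change. Direction and prefix were compared with Fisher's exact test over probes, and within 20 bins of mean signal with the Mantel-Haenszel test. The control probes of GAPDH and PGK1, 10 spots each per array, were averaged and compared with an exact permutation test over all 20 assignments of the arrays.

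On data simulated for the resistant against sensitive comparison from the means and residual spread of 30917 tested probes, with 200 probes changed, limma recovered 66 of 100 probes changed 2-fold and 92 of 100 changed 4-fold, with 4 false calls. The simulation had far fewer changed probes than the arrays did.

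Neither the files nor the gene name tables used here pair the hs- and lnc-prefixed identifiers with genes. The comparisons of coding with noncoding genes, the gene list tests and the naming of genes that had been fixed before the data were examined could therefore not be run, and counts per probe prefix took their place after the data had been seen. The rule for named genes was to take those with the largest log2 change each way among genes past the threshold, with no overlap between groups and well above background on all 3 arrays of the higher group. It was applied to probes and limited to 1 per prefix and direction, since an identifier without a gene name says little. The mean spot signal was not among the columns used here, so the median spot signal took its place in the normexp alternatives.

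Alternatives fixed before the data were examined were quantile normalization, median centring, normexp with an offset of 50 before either scaling, no filter on dim probes, a filter over all 6 arrays, an intensity trend with robust eBayes, array weights, the replicate number as a block, the slide as a random block, the authors' value table, and leaving out each array. Cyclic loess between arrays, a test with the 179 probes of other prefixes, the scalings of the control probes, counts with one-group probes at their bound, and 1 floor for all arrays were added after seeing the data.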

Results

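RNA was profiled in U251, an established human glioblastoma cell line, in a temozolomide-resistant and a temozolomide-sensitive form. Temozolomide is an alkylating drug given against glioblastoma. The comparison asked which long noncoding RNAs and messenger RNAs differed between the forms. Each form was hybridised to 3 single-colour arrays, 6 in all. Each array held 54925 probes with the vendor's identifiers, of which 31741 carried an hs prefix and 23184 an lnc prefix. The files pair no probe of either prefix with a gene name and do not say what the prefixes stand for, so the counts are of probes and not of genes. The 75th percentile of the probe signals was 1117, 1054 and 1104 on the resistant arrays and 1428, 1787 and 1873 on the sensitive arrays. Probes well above background made up 52.6% to 53.2% of those on each resistant array, and 51.3%, 58.3% and 58.0% on the sensitive arrays. No spot of these probes was saturated. The number of arrays limits the precision.

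The resistant and sensitive cells differed at most of the probes tested. Of 30978 probes well above background on all 3 arrays of at least 1 group, 23209 (74.9%) changed at an adjusted p under 0.05 in limma, 12855 higher and 10354 lower in resistant cells. Changes of at least 2-fold were found at 4910 probes that were higher in resistant cells and 5057 that were lower, together 32.2% of those tested. Some of these folds were fitted against a group in which the probe was not well above background on any array. There the arrays give only a lower bound on the fold, which can be smaller than the fitted fold. With such probes held at their bound, 4799 probes were at least 2-fold higher and 4392 at least 2-fold lower, and 500 were at least 10-fold higher and 453 at least 10-fold lower. The other 7769 probes did not pass the threshold.

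The balance between higher and lower probes depended on the scaling between arrays. The median log2 change over all tested probes was 0.16 when arrays were scaled to their 75th percentile and -0.19 when they were centred on their median. Correspondingly, 55.4% of the changed probes were higher in resistant cells under the first scaling and 37.4% under the second, with 2812 probes at least 2-fold higher and 7344 at least 2-fold lower.

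The differences between the groups were larger than the spread within them. Across tested probes, Pearson's r was 0.995 to 0.997 between resistant arrays, 0.987 to 0.995 between sensitive arrays and 0.791 to 0.818 between arrays of different groups. Probes are not independent replicates. The share of tested probes at least 2-fold apart was at most 0.917% between resistant arrays, at most 4.11% between sensitive arrays and at least 28.3% between groups. At 24571 probes (79.3%) the values of the groups did not overlap, which chance alone gives at 10% of probes picked without the groups. The filter used the groups, so among the tested probes the share that chance gives can be higher, and it was not computed. The median SD of a probe was 0.085 log2 units in resistant cells and 0.17 in sensitive cells. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. All resistant arrays lay on 1 slide scanned in 1 session, and the sensitive arrays lay on 2 other slides scanned in a second session, so scan session and group cannot be told apart.

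**Figure D1:**
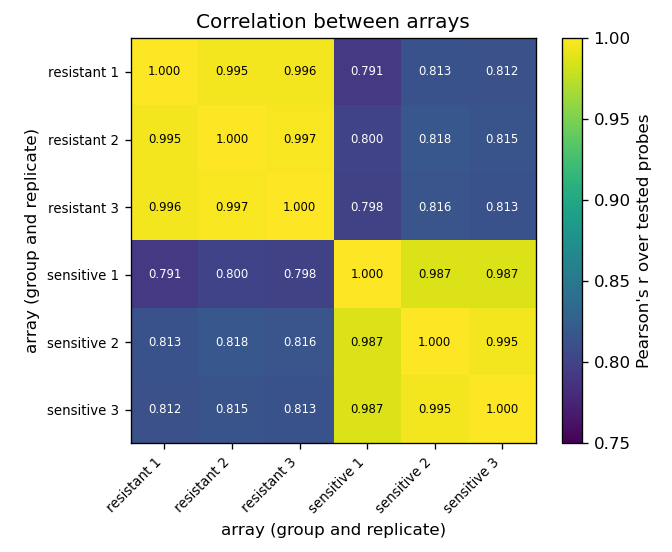
Pearson's r of scaled log2 signal across tested probes for each pair of the 6 arrays, with rows and columns giving the group and replicate and colour running from 0.75 to 1. Pairs within a group lie at 0.987 or above, and pairs between groups lie at 0.818 or below.

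Probes of the hs prefix more often fell than rose. Of 21674 tested, 16428 (75.8%) changed, 7442 higher and 8986 lower in resistant cells. At least 2-fold changes comprised 2985 higher and 4402 lower probes, so 40.4% of these were higher, and median centring gave 1911 higher and 6411 lower. The median log2 change of the hs-prefixed probes was -0.07. With probes seen in only 1 group held at their bound, 2933 hs-prefixed probes were at least 2-fold higher and 3959 lower, and at least 10-fold changes comprised 443 higher and 423 lower probes.

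Probes of the lnc prefix more often rose than fell under the 75th percentile scaling. Of 9304 tested, 6781 (72.9%) changed, 5413 higher and 1368 lower in resistant cells. At least 2-fold changes comprised 1925 higher and 655 lower probes (74.6% higher), whereas median centring gave 901 higher and 933 lower. The median log2 change of the lnc-prefixed probes was 0.53. With probes seen in only 1 group held at their bound, 1866 lnc-prefixed probes were at least 2-fold higher and 433 lower, and 239 were at least 4-fold higher and 112 lower.

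The prefixes differed in direction. Among probes changed at least 2-fold, the odds of being higher rather than lower in resistant cells were 4.33 times as large for the lnc prefix as for the hs prefix (95% interval 3.92 to 4.80, Fisher's exact test, two-sided p = 7.7e-203). This odds ratio was 7.52 (6.45 to 8.80) among the probes well above background on all 6 arrays, 3.24 under median centring and 2.403 after cyclic loess. With probes seen in only 1 group held at their bound it was 5.82 (5.18 to 6.54), and 2.68 (2.10 to 3.45), 1.99 (1.30 to 3.07) and 1.81 (1.12 to 2.98) for changes of at least 4-fold, 8-fold and 10-fold. From fitted changes it was 1.79 (1.49 to 2.14) at 4-fold, with 329 lnc-prefixed probes higher and 273 lower, and 1.97 (1.49 to 2.61) at 8-fold. The odds of changing at least 2-fold at all were lower for lnc-prefixed probes, with an odds ratio of 0.742 (0.703 to 0.783, Fisher's exact test, two-sided p = 2.3e-28). It was 0.394 under median centring and 0.376 with the authors' value table. These tests treat probes as independent. The gap between the prefixes also varied within a group. Taking each probe's deviation from its mean over the 6 arrays, the median for the lnc prefix minus that for the hs prefix was 0.34, 0.28 and 0.28 log2 units on the resistant arrays. It was -0.50, -0.18 and -0.23 on the sensitive arrays. The groups thus differed by 0.60, and the sensitive array on its own slide differed from the mean of the other two sensitive arrays by -0.30. Without that array, sensitive replicate 1, the count of lnc-prefixed probes at least 2-fold higher was 1486 and that of lower probes 642.

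**Figure D2:**
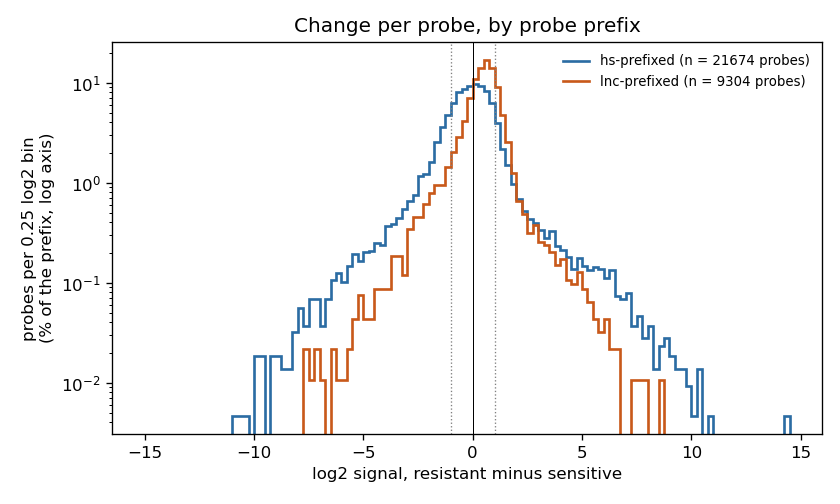
Distribution of the fitted log2 signal difference, resistant minus sensitive (a lower bound does not replace it for probes seen in only 1 group), for the 21674 hs-prefixed and 9304 lnc-prefixed probes tested, as the percentage of each prefix per bin of 0.25 log2 units on a log axis, with dotted lines at a 2-fold change. The lnc-prefixed distribution has its median at 0.53 and the hs-prefixed distribution at -0.07 under the 75th percentile scaling, and under median centring the lnc-prefixed counts of at least 2-fold changes turn to 901 higher and 933 lower.

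Some probes were well above background in only 1 of the groups. There were 988 such probes seen on all 3 resistant arrays and no sensitive array, of which 669 carried the hs prefix and 319 the lnc prefix. Conversely, 2188 were seen on all 3 sensitive arrays and no resistant array, 1552 of the hs prefix and 636 of the lnc prefix. These probes were picked by the group in which they were seen, so a call in that direction was largely set by the choice and is no separate support. All 988 passed the test as higher in resistant cells. Of the 2188, 2022 passed as lower in resistant cells, 1 passed as higher and 165 did not pass. At 227 of the 2022, the mean in sensitive cells was not above the level in resistant cells that sets the bound, so no fold and no direction is given for them at the bound. The floor of the scaled values differed between the groups. The lowest scaled log2 signal that counted as well above background was -3.22, -3.19 and -3.25 on the resistant arrays. It was -3.70, -3.93 and -4.07 on the sensitive arrays. These floors are relative to each array's 75th percentile, which was higher on the sensitive arrays (1428, 1787 and 1873) than on the resistant arrays (1117, 1054 and 1104). With -3.19 as 1 floor for all arrays, 2284 tested probes lay above it on the resistant arrays only and 1544 on the sensitive arrays only, so the order of these counts depends on the floor. For the other probes of this class the fold is given as a lower bound, set by the lowest signal that counted as well above background on each array of the dim group. The bound reached 10-fold at 268 probes in resistant cells and 288 in sensitive cells. It reached 100-fold at 28 and 29 probes, all with the hs prefix. Among the 25379 probes well above background on all 6 arrays, 2898 were at least 2-fold higher and 3261 at least 2-fold lower in resistant cells.

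The probes named by the rule for genes, adapted to probes and applied to fitted log2 change, all belonged to this class. When ranked instead with one-group probes at their bound, both probes named as higher were rank 1 of their prefix and direction, and the hs-prefixed and lnc-prefixed probes named as lower were rank 3 and rank 2. The hs-prefixed probe PH_hs_0036800 was at least 4883-fold higher in resistant cells, where its processed signal was 356514 ± 23693 (SD, n = 3) against 24.8 ± 1.69 in sensitive cells, not well above background. Its adjusted p was 1.6e-09 in limma. The lnc-prefixed probe PH_lnc_0017105 was at least 95.4-fold higher, with a signal of 6959 ± 179 in resistant cells and 25.1 ± 1.84 in sensitive cells, not well above background (limma adjusted p = 9.9e-09). In the other direction, PH_hs_0028680 was at least 391-fold lower in resistant cells, with a signal of 24.3 ± 0.31 there, not well above background, and 71619 ± 13091 in sensitive cells (limma adjusted p = 2.1e-09). PH_lnc_0006546 was at least 47.5-fold lower, with 27.5 ± 0.82 in resistant cells, not well above background, and 8598 ± 54.7 in sensitive cells (limma adjusted p = 7.2e-09).

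The arrays carried control probes for 2 genes named in the files, GAPDH and PGK1, which encode the glycolytic enzymes glyceraldehyde-3-phosphate dehydrogenase and phosphoglycerate kinase. Each gene had a probe named for its 5′ end and a probe named for its 3′ end, with 10 spots of each per array. After scaling to the 75th percentile, the log2 signal in resistant cells minus that in sensitive cells was 0.68 for GAPDH 3′, 0.60 for GAPDH 5′, 0.66 for PGK1 3′ and 1.28 for PGK1 5′. Without scaling between arrays the differences were 0.049, -0.031, 0.031 and 0.65. GAPDH 5′ thus changed sign, at a value within the spread of the arrays. In an exact permutation test, GAPDH 3′, GAPDH 5′ and PGK1 3′ then gave p = 0.7 each and PGK1 5′ gave p = 0.1. The group difference of the former probes therefore depended on the scaling. The scaled values of the groups did not overlap for any of the 4 probes, and each gave p = 0.1 in a two-sided exact permutation test, the smallest value that 3 against 3 arrays allow. Within an array the PGK1 5′ log2 signal minus the 3′ log2 signal was -1.64 ± 0.10 (SD, n = 3) in resistant cells and -2.26 ± 0.33 in sensitive cells, an unequal change of 0.62 (exact permutation p = 0.1). For GAPDH the unequal change was -0.08, or 0.02 under quantile normalization (exact permutation p = 0.1 for the former). The PGK1 difference between the ends thus moved with the groups in which the changed probes were counted.

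**Figure D3:**
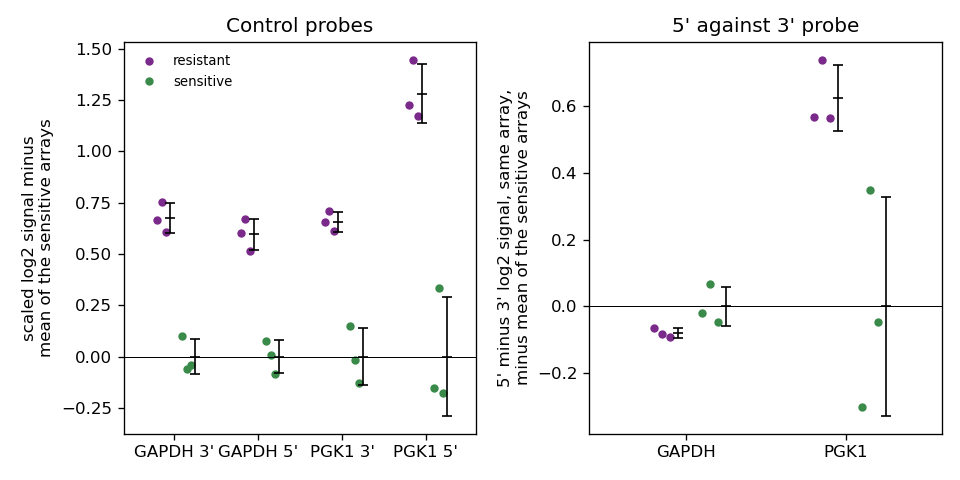
Control probes of GAPDH and PGK1 on the 3 resistant and 3 sensitive arrays, as scaled log2 signal minus the mean of the sensitive arrays for each probe (left) and as 5′ minus 3′ log2 signal within an array minus the mean of the sensitive arrays (right), where points are arrays and bars are the mean ± SD. Resistant minus sensitive is 1.28 for PGK1 5′ and 0.60 to 0.68 for the other probes. Without scaling the latter lie at -0.031 (GAPDH 5′) to 0.049, each with exact permutation p = 0.7. The 5′ minus 3′ change is 0.62 for PGK1 and -0.08 for GAPDH, which turns to 0.02 under quantile normalization.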

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

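Except for the comparison of the prefix gap between slides, whose prediction was fixed first, the tests of explanations in this part were chosen after the results were seen.

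A signal outside the main measurement was found at the control probes. The PGK1 5′ minus 3′ log2 signal, which enters no test across probes, was 0.62 higher in resistant than in sensitive cells. A shorter labelled product in the sensitive samples is a candidate explanation, since it would lower signals far from the 3′ end. The GAPDH change was -0.080 under the main scaling, opposite in sign to that of PGK1, and -0.103 to -0.047 when 1 array was left out. Scaling an array by 1 value cannot alter a difference within that array, so median centring and no scaling are no further check. Quantile normalization, which can alter it, gave 0.02, and normexp with quantile normalization gave -0.002, so the opposite sign depended on the processing. The distance of the probes from the 3′ end is not given in the sources used here, so this explanation and an unequal change of PGK1 transcripts in resistant cells cannot be told apart.

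Changes were also seen at probes outside the authors' value table, at a share no higher than among the main probes. Of the 179 probes of other prefixes that Feature Extraction did not mark as controls, 97 were tested and 66 changed in limma, 14 at least 2-fold higher and 5 at least 2-fold lower in resistant cells. These are 68.0% changed and 19.6% changed at least 2-fold, against 74.9% and 32.2% of the hs- and lnc-prefixed probes, a difference that was not tested. Of the 97, 44 shared their number with a tested hs-prefixed probe and followed its log2 change (Pearson's r of 0.991), so they may repeat it. Among these 44, 2 were at least 2-fold higher and 4 at least 2-fold lower.

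The number of changed probes was large for 2 forms of 1 cell line. The real grouping gave 23209 changed probes in limma, 1 of 10 splits of the 6 arrays reached that number, and the highest of the others was 0 (8 to 169 at an unadjusted p under 0.05), but 10 splits are too few for a share under 0.05. Every other split puts arrays of both groups on each side, so the group difference enters the spread within a side and lowers the calls. The counts of those splits are therefore no baseline for chance. A trend with brightness from scanning or labelling is argued against as the whole cause, since cyclic loess kept 80.2% of the 2-fold calls past both thresholds in the same direction. Sensitive replicate 1, alone on its slide, differed by 2-fold from the mean of sensitive replicates 2 and 3 at 1218 probes. This is 12.1% of the 10033 between groups. It differed by 10-fold at 5 probes, against 1527 between groups by fitted change (500 higher and 453 lower at bounds). A difference of that 1 array cannot be told apart from one of its slide. Scan session follows the groups, so a difference of session, culture or extraction cannot be told apart from resistance. Cultures that had diverged, or differed in origin, may also give such a number, and the highest correlation between groups, 0.818, decides nothing without a pair of cultures of known relation. Resistance to temozolomide, the difference the design names, stays open beside these.

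The excess of higher lnc-prefixed probes is the other pattern weighed. The lower brightness of these probes is argued against as the whole cause, since the odds ratio was 3.61 (3.254 to 3.999) within bins of mean signal and the lnc-prefixed share of higher probes was above the hs-prefixed share in 20 of 20 bins. The least filled bin held 14 lnc-prefixed probes changed at least 2-fold. A brightness-dependent trend between arrays is likewise argued against as the whole cause of the difference between the prefixes. The odds ratio after cyclic loess was 2.403 (2.17 to 2.66). The lnc-prefixed excess itself shrank, to 1099 probes at least 2-fold higher and 910 lower, from 1925 and 655 under the main scaling. The hs-prefixed counts after cyclic loess were 2373 higher and 4722 lower. Such a trend may therefore account for part of the excess. Variation between slides stays open. The prefix gap of sensitive replicate 1, alone on its slide, differed from that of sensitive replicates 2 and 3 by 49.1% of the difference between groups. Array and slide cannot be told apart there. A technical shift of that kind may account for part of the excess, as may a difference tied to resistance.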

How the results depend on the processing

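The cyclic loess setting, the counts at bounds, the single floor, the counts per prefix, the odds ratios and the control probe scalings were chosen after seeing the data. The count of changed probes stayed within 1.5 times its main value in every setting but 1, and no probe was called in the opposite direction in any setting. Without a filter on dim probes 38105 of 54925 probes changed, 26980 higher and 11125 lower, with 3092.0 lnc-prefixed probes at least 2-fold higher. Restricting the test to probes well above background on all 6 arrays left fewer probes and gave 2900 higher and 3261 lower at least 2-fold, with 1827 hs-prefixed higher, 1073 lnc-prefixed higher and 236 lnc-prefixed lower. Median centring gave 2812 higher probes, 1911 hs-prefixed and 901 lnc-prefixed, and the authors' value table, also centred on the median, gave 2664, 1849 and 815. Of the changed probes, 36.8% were higher with that table. The median log2 change fell to -0.19 and -0.20, but the table also differs in background correction, so the cause of its shift was not tested apart. Holding one-group probes at their bound gave 433 lower lnc-prefixed probes. With -3.19 as 1 floor for all arrays, 2284 tested probes lay above it on the resistant arrays only. Some of these could still be well above background on sensitive arrays, whose own floors were lower. After normexp and quantile normalization, 1025 lnc-prefixed probes were at least 2-fold higher and 613 lower. After cyclic loess these counts were 1099 and 910, and the cause was not tested. The odds ratio of higher against lower stayed on its side of 1 in every setting, and the 4 named probes kept their direction and call where tested (not under the filter over all 6 arrays).

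GAPDH 5′ turned to -0.031 without scaling between arrays and the GAPDH 5′ minus 3′ change to 0.022 after quantile normalization; the cause was not tested. Of the other results across settings, 165 counts and odds ratios and 128 values of single probes kept their direction and side of the threshold or stayed within their margin, and 12 values of control probes moved by more than 1 SD in the same direction.

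Leaving out 1 array gave 21029 to 24127 changed probes, 4208 to 5459 at least 2-fold higher and 4822 to 5250 lower. For the hs prefix these ranges were 2722 to 3212 higher and 4180 to 4581 lower, and for the lnc prefix 1486 to 2247 and 642 to 669. With the slide as a random block, 18952 probes changed. No slide held both groups, so this setting cannot separate a slide or session effect from the group difference. With the replicate number as a block, 22037 changed. The numbers did not pair the samples, since the correlations of same-numbered deviations were -0.33, -0.13 and -0.30 and 0 of 3 resistant arrays correlated best with their own number. Coding and noncoding gene counts, gene list tests and their own alternatives were not run, since no gene names were paired with probes. Signal over background limited the test to 56.4% of the probes.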

Other observations

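Among the probes of other prefixes, 46 shared their number with an hs-prefixed probe, and 44 such pairs could be compared. The log2 change had the same sign in 38 of the 44 pairs, with a median absolute gap of 0.14 and Pearson's r of 0.991 across pairs, which are not independent replicates. Of the 44 number-matched probes, 2 were at least 2-fold higher and 4 at least 2-fold lower in resistant cells in limma.

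Of the 24 probes with the prefix AM_c, exactly 1 was bright on each array. Its processed signal ranged from 83282 to 371997 over the 6 arrays, while the next brightest ranged from 65.0 to 147. Resistant replicate 1 and sensitive replicate 2 shared their bright probe, as did resistant replicate 2 and sensitive replicate 3.

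At a threshold of 8-fold, with probes seen in only 1 group held at their bound, 76 lnc-prefixed probes were higher and 38 lower in resistant cells, against 531 and 528 hs-prefixed probes.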
